A study of Mus musculus with 25 samples.

How the data were processed

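Lung RNA of C57BL/6 mice had been hybridized to Affymetrix MG-U74Av2 arrays. The 24 arrays belonged to 11 groups: calorie restriction (CR, food reduced by 2/3) for 2, 4, 12, 24, 48, 72 or 96 h with 2 arrays each, and fed controls at 0 h with 4 arrays and at 2, 4 and 12 h with 2 arrays each. Group and time were taken from the labels. The descriptions of the control arrays call the mice always fed but also carry the words for the 2/3 reduction, so their feeding is not certain; they were read as controls without restriction. Each array carried a number and a letter, a or b. Whether a and b were different animals or repeat arrays of 1 RNA is not stated, so the p-values may measure only technical spread. Fed 0 h alone had 2 numbers, 1 and 2, with letters a and b each.

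The deposited values were linear probe set intensities. Tested on the values, they were all above 0, had no gaps, and shared 1 trimmed mean after the lowest and highest 2% of probe sets were left out, so the authors had already scaled each array. The software behind them is not given in the sources used here. A further array, of another platform with 45101 probe sets, was made with MAS5 per the submitters' processing notes, without a version. Its deposited values were intensities with another trimmed mean. Its title and its description give different treatments, so it was placed in no group and entered no comparison.

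Each array was scaled to the median of the 24 array medians. Values under the 25th percentile of all scaled values, a signal of 80.37, were raised to that floor, and log2 was taken. Such a floor compresses changes of dim probes, and a group with at least 50% of its arrays at the floor gives only a lower bound of a fold. Of 12488 probe sets, 66 controls were left out. Of the other 12422, 10833 had 1 gene symbol in the annotation table (August 2016), 396 had several and 1193 had none. The Entrez identifiers of 10817 of those with 1 symbol were found in the mouse reference gene table (GRCm38.p6), which was used for gene names only. The filter kept the 7440 probe sets that reached the array's own median on at least 2 arrays; 6725 of them had 1 symbol, for 5706 genes.

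Group means were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend; 13 residual degrees of freedom). A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 7440 probes. All tests were two-sided. Folds are ratios of geometric means with 95% confidence intervals, while levels are arithmetic means of scaled signal with the SD over arrays. Early times were compared with the fed group of the same hour. Late times, 24 to 96 h, were compared with fed 0 h, which by the labelled hours has the same clock time. The mean of the 3 early and of the 4 late differences, and fed 12 h against fed 0 h, were the main comparisons. Moderated F tests compared the effects between early times and between late times.

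The model, its settings, 35 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, 1 probe per gene, the brightest) and Benjamini-Hochberg over the 34 lists with at least 3 measured genes. Each list was tested again with a correlation estimated from the data. The genes named were, for each main comparison, the 10 largest rises and 10 largest falls among called genes whose change had 1 direction at every time (for fed 12 h, both arrays beyond all fed 0 h arrays). For each single time they were the 3 largest in each direction with both arrays beyond every control array. The 6 smallest p of an F test, up to 4 members of a list by smallest p, and clock and cold-inducible genes were named as well. Further list members and genes named outside this rule were chosen after their values were seen.

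Alternatives covered normalization, floor, filter, variance model, array weights, the groups in the fit, the letter as a replicate block, letters averaged, other fed controls, other list tests, and each array left out. Separate fed 0 h numbers, a block for the signal range of the arrays, and 4 and 12 h alone were added after the data were seen. The pipeline was tested on simulated data with 200 of 7440 probes changed. In the late mean it recovered 15 of 67 probes changed by 0.5 log2, 51 of 67 changed by 1 and 66 of 66 changed by 2, and it called 7 of 7240 unchanged probes. In the early mean the recovered numbers were 19, 53 and 66, with 13 false calls, and for CR 2 h against fed 2 h they were 2, 21 and 51, with 4 false calls. A list raised by 0.5 log2 was called, with none of the 33 others. The simulated values were independent between genes and between arrays, and the fed 0 h numbers did not differ in them. These low numbers of false calls therefore need not hold for the real arrays. The number of arrays, mostly 2 per group, limits the precision of every value.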

Results

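Gene expression was measured in lung tissue of C57BL/6 mice, an inbred laboratory strain, during the first 4 days after food was reduced by 2/3. Per the labels, the project concerned the loss of alveoli, the gas-exchange units of the lung, under this diet. CR lungs were taken at 2, 4, 12, 24, 48, 72 and 96 h (2 arrays each), and lungs of fed mice at 0 h (4 arrays) and at 2, 4 and 12 h (2 arrays each). The deposited median signal was 300.2 to 342.3 per array, and scaling multiplied the arrays by 0.920 to 1.05. Arrays a and b of 1 group and number correlated at r = 0.940 to 0.976 across probes. For 10 of the 24 arrays, however, the correlation with an array of another group was higher than that with the a or b partner. Because a and b may be repeat arrays of 1 RNA, the p-values below may measure only technical spread.

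The arrays differed in 2 ways that the groups do not explain. Their highest signal was 74440 to 99040 in 12 arrays (fed 0 h number 1, fed 12 h, CR 2, 12, 24 and 48 h) and 31600 to 54310 in the other 12 (fed 0 h number 2, fed 2 and 4 h, CR 4, 72 and 96 h). This range is set by the single highest probe set of each array. Sftpc, the surfactant protein C gene of alveolar type II cells, was at 93040 ± 6590 in fed 0 h number 1 and at 46880 ± 6099 in number 2 (mean ± SD, 2 arrays each). On the number 1 arrays Sftpc was itself the highest signal, so it is no independent sign of the range. The fed 0 h numbers correlated at r = 0.854 to 0.871 with each other and at 0.956 and 0.959 within themselves. Between them 2969 of 7440 probes differed (limma, adjusted p under 0.05), 1486 higher in number 1 and 1483 lower. Oxidative phosphorylation genes were higher in number 1 (46 of 64; adjusted p = 3.1e-12), as were genes of ribosomal proteins (20 of 25; 1.73e-08), the proteasome (23 of 32; 3.68e-06) and macrophages (13 of 22; 0.000102). Genes of cholesterol synthesis (5 of 14; 0.0473) and erythroid cells (5 of 11; 0.0273) were higher too. Lower in number 1 were genes of the extracellular matrix (18 of 39; 0.00191), retinoid and alveologenesis signalling (12 of 30; 0.0273), smooth muscle (5 of 14; 0.0473) and the circadian clock (7 of 18; 0.0473). The late counts, and the lists and genes that this changed most, are therefore also given against each number or within each signal range. The ratio of 3' to 5' probe sets of actin ran from 1.24 to 3.81, and that of Gapdh from 1.01 to 2.15. The Gapdh ratio was 1.76 to 2.02 on the 4 fed 0 h arrays, the control of every late comparison, and 1.95 and 2.15 at CR 48 h, against 1.01 to 1.66 on all other arrays. The actin ratio was 1.87 to 2.31 in fed 0 h, 2.69 and 3.81 at CR 48 h, 2.77 on CR 24 h 1a, 2.37 on fed 4 h 1b and on fed 12 h 1b, and 1.24 to 2.04 on the other arrays. Late changes, and fed changes from 0 h, therefore also compare arrays that differ in 1 or both of these signs of RNA quality.

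From the first day of CR on, the list of genes that glucocorticoid hormones induce in many tissues was higher than at fed 0 h, by a median log2 change of 0.71 at 24 h and 1.07 in the late mean, and some members rose far more. Zbtb16, a zinc-finger transcription factor, stood at 806 ± 551 signal units in fed 0 h (mean ± SD, 4 arrays) and at 7645 ± 1283 over CR 24 to 96 h (8 arrays), a rise of 11.7-fold (95% confidence interval 7.35 to 18.5, adjusted p = 7.36e-07). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 9.41-fold (7.39 to 12; 6.76e-10), from 336 ± 115 to 3263 ± 1295. Pdk4, the kinase that shuts off pyruvate dehydrogenase when fat is burned, rose 7.23-fold (5.62 to 9.31; 3.28e-09), from 290.3 ± 92.5 to 2040 ± 344. In the late mean 11 of 25 interferon response genes fell and 1 rose, and 6 of 15 B-cell and 5 of 31 cell-cycle genes fell. With an estimated correlation the B-cell list did not pass (0.129), and at 24 h alone no gene of these 3 lists passed.

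Among the other large rises, Map3k6, a kinase of the MAP kinase cascade, rose 10.3-fold (7.11 to 14.9; adjusted p = 5.58e-08) from 206 ± 116. Sorbs3, which encodes the adhesion adaptor vinexin, rose 6.97-fold (adjusted p = 0.000686), although 1 fed 0 h array lay far above the other 3. Inpp5d, a phosphatase of blood-cell signalling, rose 5.32-fold (0.000208) and Dll1, a Notch ligand, rose 4.23-fold (0.00632). Per1, a clock gene with a glucocorticoid response element, rose 4.08-fold (1.08e-06), from 337 ± 92 to 1391 ± 462. Cdkn1a, the cell-cycle inhibitor p21, rose 3.95-fold (5.58e-08), from 943 ± 171 to 3807 ± 1011, and its other probe rose by 1.34 on the log2 scale. Tcf25 was at the floor on all 4 fed 0 h arrays and rose at least 5.73-fold (0.00173). The other probes of Tcf25 and Inpp5d did not pass, at log2 changes of 0.07 (adjusted p = 0.861) and -0.34 (0.387).

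The largest fall was that of Plac8, from 6449 ± 4711 to 1290 ± 471, 4.07-fold lower (adjusted p = 0.00064), but Plac8 was at 10510 ± 626 in fed 0 h number 1 and at 2389 ± 504 in number 2. Csrp3, the muscle LIM protein, fell 3.03-fold (0.00209), from 887 ± 240 to 322 ± 145. Csf3, which encodes the neutrophil growth factor G-CSF, fell 3.03-fold (0.00277) and Thrsp, a regulator of fat synthesis, fell 2.97-fold (0.00156). Ms4a1, the B-cell antigen CD20, fell 2.87-fold (0.00185), from 1393 ± 688 to 449 ± 132, and its other probe fell by 1.32 on the log2 scale. Gzma, the granzyme A of cytotoxic lymphocytes, fell 2.85-fold (0.00791). Chrna7, a nicotinic acetylcholine receptor subunit, fell 2.89-fold (0.0199) and Mea1 3.09-fold (0.0205). Ift46, of intraflagellar transport, fell 2.87-fold (0.0192), and Stt3a, a subunit of the oligosaccharyltransferase, fell at least 2.85-fold (0.00323). The other probes of Mea1, Ift46 and Stt3a did not pass, at log2 changes of -0.34, -0.20 and -0.37.

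**Figure D1:**
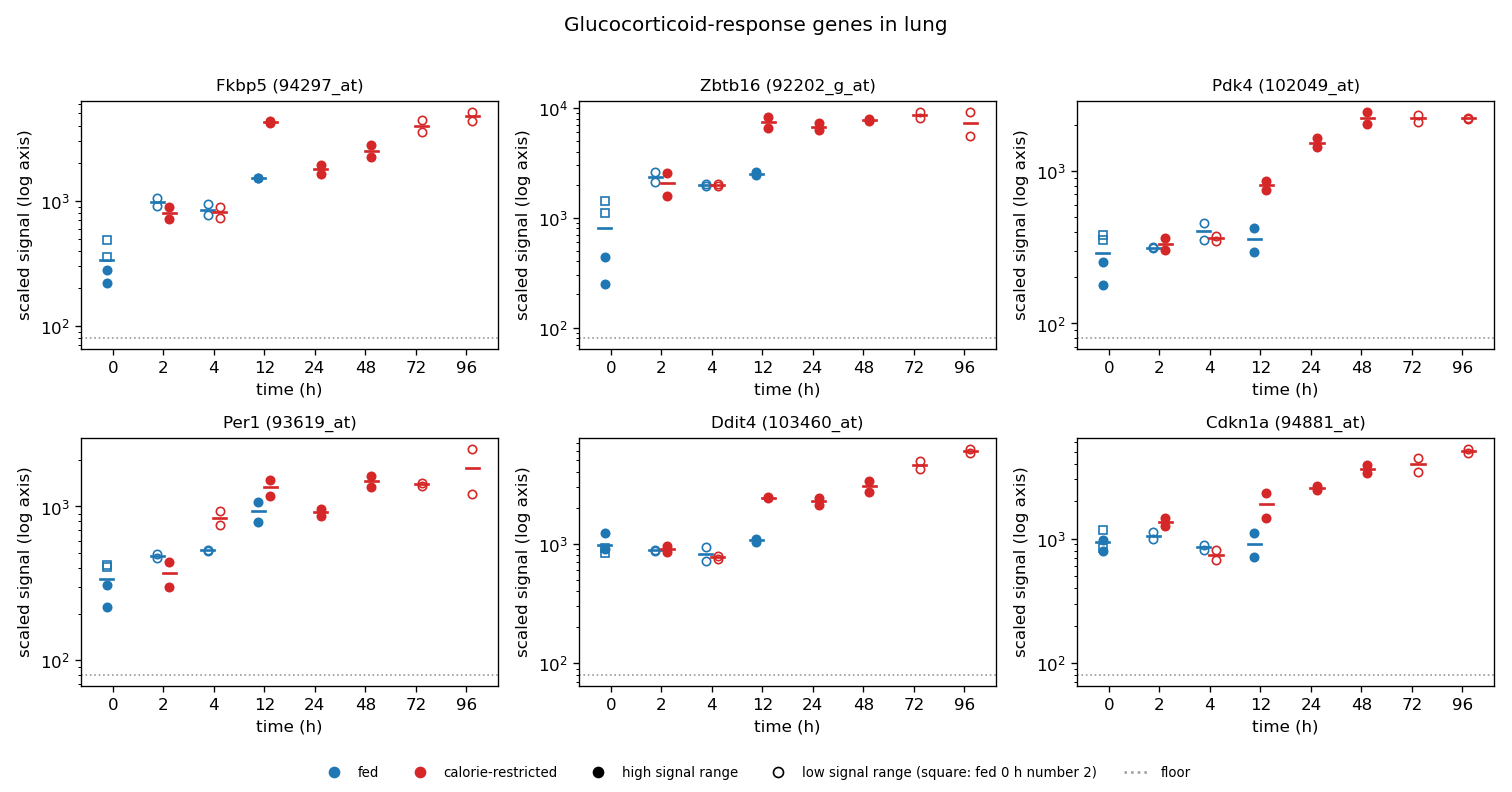
Scaled signal per array (log axis) of Fkbp5, Zbtb16, Pdk4, Per1, Ddit4 and Cdkn1a against hours; blue points are fed and red CR arrays, filled points have the high and open points the low signal range, squares are fed 0 h number 2, short bars are group means and the dotted line is the floor. Fkbp5 averaged 336 in fed 0 h, 1530 in fed 12 h, 4280 in CR 12 h and 3263 over CR 24 to 96 h, and Zbtb16 averaged 806, 2523, 7402 and 7645 in the same groups.

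In the late mean 733 probes rose and 613 fell, 1346 of 7440. Against fed 0 h number 1 alone 3679 changed and against number 2 alone 577. Within the high signal range, CR 24 and 48 h against number 1, 3423 changed, and within the low range, CR 72 and 96 h against number 2, 793 changed. Of the 733 rises 181 held against each number and 168 within each range. Of the 613 falls 88 and 93 did so. Against number 2 the log2 changes of Dll1 (0.68, adjusted p = 0.195), Mea1 (-0.43, 0.564), Ms4a1 (-0.87, 0.0572), Gzma (-0.49, 0.283) and Chrna7 (-1.46, 0.127) did not pass, and against number 1 that of Ift46 (-1.07, 0.0883) did not. Sorbs3 (3.58 against number 1 and 2.02 against number 2), Inpp5d (3.47 and 1.35), Thrsp (-2.37 and -0.78) and Plac8 (-3.10 and -0.95) passed against each, but with log2 changes that differ widely. Zbtb16 passed against each too, with log2 changes that also differ widely, 4.5 against number 1 and 2.59 against number 2. Fkbp5 (3.61 against number 1 and 2.86 against number 2), Pdk4 (3.25 and 2.46), Per1 (2.36 and 1.7) and Cdkn1a (2.08 and 1.89) passed against each. Leaving out 1 array moved the count to between 542 (without fed 0 h 1b) and 2248 (without fed 0 h 2a). It was 595 without fed 0 h 1a, 857 without CR 96 h 1b and 2155 without fed 0 h 2b. With a and b averaged to 1 sample and the late times taken as 1 group, 27 probes passed, 26 of them higher. Among them were Zbtb16, Map3k6, Fkbp5, Pdk4, Per1, Cdkn1a, Lox, Klf9, Angptl4, Lyve1 and Klf2. Differences between the late times then enter the spread, and fewer degrees of freedom remain.

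Of the 34 lists tested, 15 shifted in the late mean, 6 up and 9 down. The glucocorticoid response list shifted most: 19 of its 24 measured genes rose, none fell and 5 did not pass, with a median log2 change of 1.07 (adjusted p = 1.32e-16; 0.00011 with an estimated correlation). Adjusted over the list alone, 19 rose and 1 fell. Besides Zbtb16, Fkbp5, Pdk4, Per1 and Cdkn1a, these included Ddit4, an inhibitor of mTORC1 signalling (3.82-fold, 3.28e-09), Errfi1, an inhibitor of EGF receptors (2.54-fold, 5.58e-08), Nfkbia, the NF-kappaB inhibitor (2.34-fold, 7.41e-07), and the metallothioneins Mt1 (1.9-fold, 0.000105) and Mt2 (1.75-fold, 2.94e-05). The list was higher within the high signal range (15 of 24 rose and 1 fell, 5.42e-06) and within the low one (18 rose, none fell, 3.91e-21). It was also higher against fed 2, 4 and 12 h together (3.38e-20). It rose at every single late time, by 12 genes at 24 h, 14 at 48 h, 16 at 72 h and 19 at 96 h. Of its 24 genes 8 were in another list too.

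Genes of fuel use followed. Among fatty acid oxidation and PPAR target genes 5 of 24 rose and none fell (adjusted p = 0.00717; 0.26 with an estimated correlation), and 9 rose and 1 fell adjusted over the list alone. Besides Pdk4 they were Angptl4, a secreted inhibitor of lipoprotein lipase (3.72-fold, 1.05e-08), Lpl, lipoprotein lipase itself (3.27-fold, 1.05e-08), Acot1, an acyl-CoA thioesterase (2.43-fold, 1.08e-06), and Cpt1a, which brings fatty acids into mitochondria (1.99-fold, 0.00224). Against fed 0 h number 1 the list's adjusted p was 0.363 and against number 2 1.39e-05. Of 33 FOXO, atrophy and autophagy genes 10 rose and 1 fell (0.0279; 0.369 with an estimated correlation), 10 and 2 adjusted over the list alone, led by Ddit4, the transcription factor Foxo3 (2.58-fold, 0.000326) and Txnip (1.57-fold, 7.5e-05), with Atg5 1.46-fold lower. Against number 1 its adjusted p was 0.614.

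Endothelial genes were higher. Of 27, 13 rose and 1 fell (median log2 0.56, adjusted p = 4.64e-05; 0.235 with an estimated correlation), and 17 and 2 adjusted over the list alone. Lyve1, a hyaluronan receptor of lymphatic endothelium, rose 3.31-fold (6.09e-08), Klf2, a flow-responsive transcription factor, 2.94-fold (9.31e-05), and Flt1, a VEGF receptor, 2.13-fold (0.00912), while Emcn fell 1.42-fold. The list shifted up against number 1 (0.00653) and number 2 (0.000173), and within the high (0.00141) and the low range (0.028). It was also higher in the fed 2, 4 and 12 h groups than in fed 0 h (9 of 27 rose, median log2 0.35, 0.00018). Late CR lay above those fed groups by less, at median log2 0.11 (7 rose, 2 fell, 0.0475). Of 29 immediate early genes 9 rose and 2 fell (0.00603; 0.15 with an estimated correlation), 11 and 2 adjusted over the list alone. Klf4 rose 2.35-fold, Ccn2, a matricellular growth factor, 2.31-fold, and Fos 1.99-fold, and against number 2 the list's adjusted p was 0.075. The circadian clock list (4 of 18 rose, 1 fell; 0.0493; 0.44 with an estimated correlation; 7 and 2 adjusted over the list alone) is described with the fed times.

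Of the immune lists, those of the interferon response, B cells, and NK and cytotoxic T cells were lower than at fed 0 h. The T-cell (adjusted p = 0.891), neutrophil (0.896), cytokine (0.896) and macrophage lists (0.092) did not shift against fed 0 h. Against fed 2, 4 and 12 h together, macrophage (13 of 22 fell, 1 rose, 1.46e-10) and T-cell genes (4 of 10 fell, 0.00912) were lower. Against those groups the neutrophil (0.419) and cytokine lists (0.299) did not shift. Macrophage genes were lower within the high signal range (5.35e-06) and higher within the low one (0.00192). Within the low signal range neutrophil genes were higher (4 of 11 rose, 0.0194). Of 25 interferon response genes 11 fell and 1 rose (median log2 -0.32, adjusted p = 1.13e-05; 0.0326 with an estimated correlation), with the same numbers adjusted over the list alone. Iigp1, an interferon-induced GTPase, fell 2.1-fold (4.83e-05) from 1911 ± 374 to 922 ± 235, Isg15, the ubiquitin-like modifier, 2.0-fold (0.00112) from 1047 ± 262 to 529 ± 139, and Ifi27l2a 2.54-fold (0.00965), while Trim25 rose 1.48-fold. The list was lower within the high (0.0334) and the low range (1.1e-06). Of 15 B-cell genes 6 fell and none rose (median log2 -0.65, 4.64e-05; 0.129 with an estimated correlation), 9 adjusted over the list alone. Cd79b, of the B-cell receptor, fell 2.63-fold (0.00672), Fcer2a, the low-affinity IgE receptor, at least 2.38-fold (0.0104), and Blnk, a receptor adaptor, 1.93-fold (0.00748). Cd79b was at 2860 ± 179 in fed 0 h number 1, at 880 ± 519 in number 2 and at 608 ± 230 in late CR. The list was lower within the high (0.00179) and the low range (0.0152). Of 5 NK and cytotoxic T-cell genes Gzma, Klrd1 and Gzmb fell (0.0281; 0.369 with an estimated correlation; 3 adjusted over the list alone), and against number 2 the adjusted p was 0.455.

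Of 31 cell-cycle genes 5 fell and none rose (median log2 -0.31, adjusted p = 0.00357; 0.0326 with an estimated correlation), also 5 adjusted over the list alone: Stmn1, a microtubule regulator (1.64-fold, 0.00257), Ube2c, Mcm5, Kif22 and Ccnb2. Its adjusted p was 0.0767 against number 1 (median log2 -0.47, 11 fell, 3 rose) and 0.0096 against number 2 (-0.26, 2 fell, 0 rose). Of 24 cardiac and skeletal muscle genes 7 fell and none rose (0.00469; 0.216 with an estimated correlation), 8 fell and 2 rose adjusted over the list alone, led by Csrp3, Myl7, the atrial myosin light chain (2.38-fold, 7.36e-06), and Myl4 (2.01-fold, 2.48e-05). The muscle list had an adjusted p of 0.662 within the high range (median log2 -0.30, 6 fell and 3 rose). Within the low one it was 8.2e-06 (-0.46, 8 fell and 0 rose). The list was lower in fed 2, 4 and 12 h than in fed 0 h (6 of 24 fell, 0.000609). Late CR had a median log2 difference of -0.08 from those fed groups (3 rose, 1 fell, 0.726).

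Genes for mitochondria and protein turnover were lower against the pooled controls and differed between the fed 0 h numbers. Of 64 oxidative phosphorylation genes 27 fell and 1, Sdha, rose (median log2 -0.58, adjusted p = 8.88e-12; 0.369 with an estimated correlation), 41 and 1 adjusted over the list alone. Atp5e, an ATP synthase subunit, fell 2.67-fold (0.00535) and Uqcr11, of complex III, 2.42-fold (0.00798). Of 25 ribosomal protein genes 7 fell (1.13e-05; 0.41 with an estimated correlation), 12 adjusted over the list alone, with Rps19 2.09-fold and Rpl13a 2.02-fold lower. Of 32 proteasome genes 6 fell (0.000378; 0.467 with an estimated correlation), also 6 adjusted over the list alone, with Psmb1 1.79-fold lower. Against number 2 the adjusted p of the 3 lists was 0.075, 0.951 and 0.954. All 3 were also lower in fed 2, 4 and 12 h than in fed 0 h: oxidative phosphorylation (30 of 64 fell and 1 rose, median log2 -0.39, 1.13e-13), ribosomal proteins (8 of 25, -0.28, 1.22e-06) and the proteasome (7 of 32, -0.25, 0.00018). Late CR lay below those fed groups by less, at median log2 -0.14 (0.000401), -0.15 (0.00433) and -0.09 (0.0653). Within the low range, oxidative phosphorylation had 2 genes lower (0.028). Of 14 cholesterol synthesis genes Mvk and Ebp fell (0.0407; 0.373 with an estimated correlation; 2 adjusted over the list alone), with 0.93 against number 2.

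**Figure D2:**
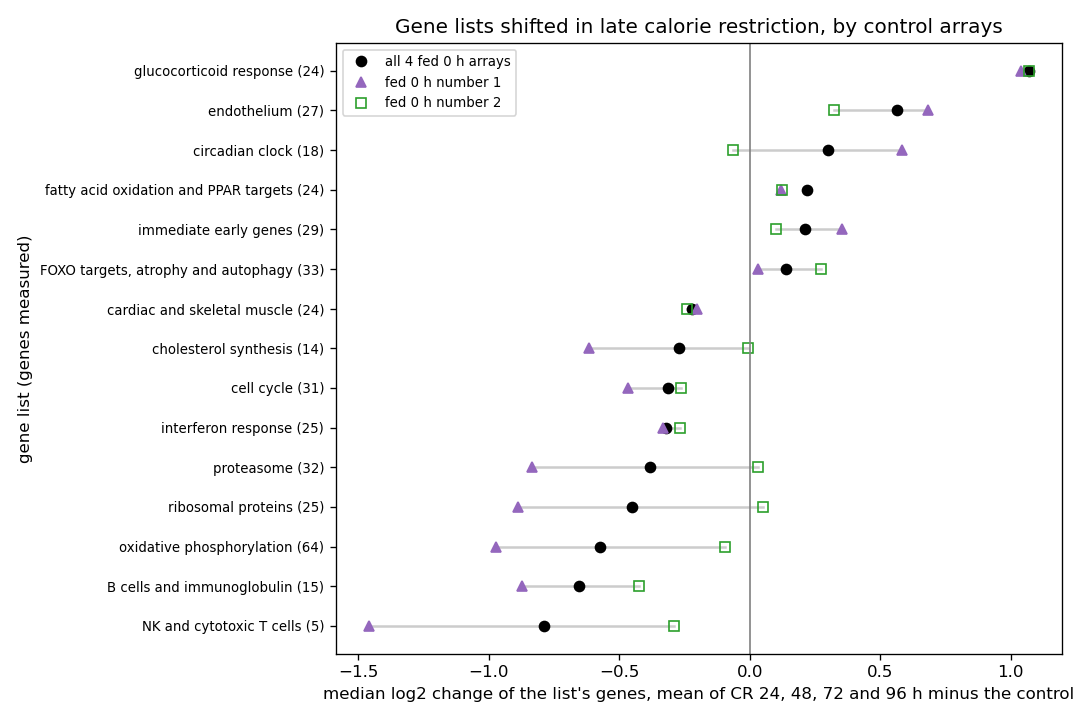
Median log2 change in the late CR mean (horizontal axis) of the 15 gene lists that shifted, each against all 4 fed 0 h arrays, against number 1 and against number 2. The glucocorticoid list has a median of 1.07 against all 4 arrays, and the oxidative phosphorylation list one of -0.58.

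Lists of alveolar structure did not shift as a whole. Of 39 extracellular matrix and elastic fibre genes 6 rose and 3 fell (adjusted p = 0.301; 9 and 3 adjusted over the list alone). Lox, the collagen and elastin cross-linking enzyme, rose 3.83-fold (7.36e-07), from 333 ± 75 to 1285 ± 327, Mfap2, of elastic fibre microfibrils, 1.65-fold (0.000208), and Eln, elastin, 1.43-fold (0.0164). Col3a1, type III collagen, fell 1.91-fold (2.21e-06) and Serpinh1, the collagen chaperone, 1.9-fold (8.25e-05). The matrix list went up against number 1 (0.0195) but had a negative direction against number 2 (0.0955), and within the ranges it was higher in the high (0.00201) and lower in the low one (0.00605). Of 10 type II cell genes Slc34a2, a phosphate transporter (1.54-fold, 0.000922), and Sftpb, surfactant protein B (1.42-fold, 0.037), rose and Fabp5 and Dlk1 fell (list 0.891). None of 8 type I cell genes passed (0.891). Of 32 apoptosis genes 8 rose and 3 fell (0.355). Bcl2l1, which encodes the survival protein Bcl-xL, rose 1.97-fold (2.74e-05) and Birc3, an inhibitor of apoptosis, 1.98-fold (0.00529), as did the death receptor Fas (1.78-fold, 0.0121) and Bcl2l11, the killer protein Bim (1.7-fold, 0.0102), while Tnfsf10, the ligand TRAIL, fell 2.3-fold (0.0089). Of 30 retinoid and alveologenesis genes 7 rose and 3 fell (0.211), with the retinoic acid receptor Rarg 2.88-fold (0.0341) and Fgfr1 2.42-fold higher (0.0209). Of this list 17 rose and 3 fell against number 1 (median log2 0.59), and 2 rose and 2 fell against number 2 (-0.06). It was higher within the high range (0.0241) but not within the low one (median log2 -0.09, 0.493).

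Taken 1 at a time, CR 24 h changed 210 probes (149 up, 61 down), 48 h 405 (188 up, 217 down), 72 h 433 (274 up, 159 down) and 96 h 483 (292 up, 191 down). These times share the fed 0 h arrays, so no overlap between them was tested. Without 1 array the 24 h count was 37 or 77 (CR 24 h 1a or 1b), 137 (fed 0 h 1b), 744 (2a) or 606 (2b), and the 48 h count 93 or 110 (CR 48 h 1a or 1b), 204, 191, 1239 or 1010 (fed 0 h 1a, 1b, 2a or 2b). The 72 h count was 115 or 61 (CR 72 h 1a or 1b), 264, 1079 or 1088 (fed 0 h 1b, 2a or 2b). The number of probes changed, CR 96 h against fed 0 h, was 83 (without CR 96 h 1b), 939 or 1017 (without fed 0 h 2a or 2b). Within the signal range 2895 probes changed at 24 h and 3142 at 48 h, both against fed 0 h number 1. Zbtb16 and Map3k6 were among the 3 largest rises at every late time, Zbtb16 with 10.4-, 12.1-, 13.4- and 11-fold, joined by Tcf25 at 24 h, Pdk4 at 48 h (7.95-fold) and Fkbp5 at 72 and 96 h (12.3- and 14.7-fold). The largest falls were Snrp1c-ps2, Cars and Stt3a at 24 h, Bik (5.71-fold), Plac8 and Grik5 at 48 h, Zfp787, Fcer2a (at least 4.22-fold) and Plac8 at 72 h, and Csrp3 (at least 5.38-fold), Plac8 and Mea1 at 96 h. The second probe of Zfp787 had a log2 change of -0.01 (adjusted p = 0.987). Between the 4 late times 43 probes differed (moderated F test), and fewer without 1 of the CR 48, 72 or 96 h arrays. CR 24 and 48 h had the high signal range and CR 72 and 96 h the low one, so this test mixes time with range. With that range as a block, or with array weights, the count was far higher, as given below. The clearest difference was that of Cyp1a1, a xenobiotic-metabolizing enzyme (adjusted p = 8.94e-05). It was at 4774 ± 1831 at 72 h and at 626 ± 52, 317 ± 151 and 539 ± 75 at 24, 48 and 96 h. Ddit4 differed too (0.00395), from 2264 ± 219 at 24 h to 5991 ± 336 at 96 h. At 72 and 96 h the muscle list (0.0461 and 0.0458) and at 96 h the immediate early (0.0186) and matrix protease lists (0.0458) also passed with an estimated correlation. The matrix protease list was likewise higher in fed 2 h than in fed 0 h (0.000996; 0.0359 with an estimated correlation) and in fed 2, 4 and 12 h together (0.0198), and late CR showed no rise over those fed groups (direction down, 0.726).

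In the first 12 h of CR, each time compared with the fed group of the same hour, few genes changed without a block for the signal range. In the mean of the 3 early times Angptl4 rose 1.67-fold (1.4 to 1.99; adjusted p = 0.0273) and Rnf20, a histone ubiquitin ligase, fell 2.24-fold (1.71 to 2.94; 0.0273). The 12 h arrays differed most. Angptl4 was at 856 ± 99, 655 ± 9 and 624 ± 176 in fed 2, 4 and 12 h, and at 936 ± 9, 876 ± 85 and 1949 ± 158 in CR. Rnf20 was at 1009 ± 131, 922 ± 127 and 718 ± 23, and at 493 ± 59, 747 ± 41 and 162 ± 34. Their other probes did not pass: Angptl4 had log2 changes of 0.53 and -0.37 and Rnf20 one of -0.06 (adjusted p = 0.999 each). No probe changed at 2 h or at 4 h (limma; 472 and 130 probes at an unadjusted p under 0.05). No probe's effect differed between 2, 4 and 12 h (moderated F test in limma; 358 at an unadjusted p under 0.05). With some alternatives, the signal range as a block among them, probes did pass this test, as given below. The fed and CR arrays of 2 h had different signal ranges. With that range as a block, which rests on the fed 0 h numbers alone, the number of probes changed, CR 2 h against fed 2 h, was 800, and that of probes changed, mean early CR effect, was 452. Over the probes that differ between those numbers, the other groups of high and low range differed by a median of 1.52% of that difference. The block thus subtracts at 2 h a difference that these groups as a whole did not show. These 2 counts therefore cannot be read as corrected for the range. With 4 and 12 h alone, where the ranges match, 1 probe passed. For Angptl4, mean early CR effect was then 1.04 log2 (adjusted p = 0.00852), and for Rnf20, mean early CR effect was -1.23 (0.132). Leaving out 1 array moved the early count of 2 to between 0 (without any 1 of 9 arrays) and 3 (without fed 2 h 1a), and it was 1 without CR 12 h 1a.

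At 12 h of CR 8 probes rose and 3 fell. Besides Angptl4 (3.18-fold, adjusted p = 0.00147), the rises were Cars, the cysteinyl-tRNA synthetase (at least 4.33-fold, 0.0329), Kdm1a, a histone demethylase (at least 4.28-fold, 0.0423), Nsmf (3.58-fold, 0.0349), Fkbp5 (2.8-fold, 0.0329), Ddit4 (2.28-fold, 0.0105), Lpl (2.03-fold, 0.0329) and Mt2 (2.01-fold, 0.0105). Rnf20 fell 4.47-fold (0.00576), Pax5, the B-cell lineage transcription factor, 4.15-fold (0.00561), from 441 ± 65 to 106 ± 15, and Rac2, a GTPase of blood cells, 1.97-fold (0.0362). Cars, Kdm1a and Nsmf were low in the fed 12 h group: they were at 81.5 ± 1.6, 80.4 ± 0 and 146 ± 86 in fed 12 h, at 354 ± 42, 346 ± 40 and 473 ± 27 in CR 12 h, and at 377 ± 124, 432 ± 117 and 581 ± 125 in fed 0 h. The count of 11 was 1 without fed 12 h 1b, 4 without CR 12 h 1a and 6 without CR 12 h 1b. Against fed 0 h in place of fed 12 h, 698 probes changed.

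The glucocorticoid response list was higher at 12 h of CR but did not shift at 2 h (median log2 0.10, adjusted p = 0.61; 0.777 with an estimated correlation) or at 4 h (0.01, 0.227; 0.898). In the early mean it was higher: none of its 24 genes passed over all probes, 7 rose adjusted over the list alone (median log2 0.29, adjusted p = 1.28e-13; 0.000318 with an estimated correlation). At 12 h Fkbp5, Ddit4 and Mt2 rose, and 11 genes rose adjusted over the list alone (1.87e-17; 8.37e-05 with an estimated correlation). At 12 h the B-cell list was lower (Pax5 fell; 3 fell adjusted over the list alone; 2.9e-06; 0.102 with an estimated correlation). Fatty acid oxidation and PPAR targets were higher (Angptl4 and Lpl rose; 4 adjusted over the list alone; 0.00651; 0.288), as were FOXO targets (Ddit4; 1; 0.00777; 0.288). In the early mean type I cell genes shifted up and B-cell genes down, with no single gene past the threshold in either way of adjustment (0.0326 each; 0.731 each with an estimated correlation).

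At 2 h, where the fed and CR arrays differ in signal range, 4 lists shifted and none of them with an estimated correlation. Oxidative phosphorylation (median log2 0.27, adjusted p = 0.000268), ribosomal protein (0.42, 0.000509) and proteasome genes (0.27, 0.0116) were higher and extracellular matrix genes lower (-0.33, 0.000253), and no member passed. Their adjusted p with an estimated correlation was 0.777, 0.777, 0.777 and 0.597. With the signal range as a block, the first 3 lists turned down (3.49e-08, 3.22e-05 and 0.000569). These 3 lists were higher in fed 0 h number 1 than in number 2, and the block subtracts that difference. The turn therefore does not show what the signal range did at 2 h. At 4 h 5 lists shifted, 1 up and 4 down, none of them with an estimated correlation. They were endothelium (0.0474; 0.898 estimated), interferon response (0.0293; 0.572), antioxidant and xenobiotic enzymes (0.0474; 0.725), oxidative phosphorylation (0.00266; 0.898) and proteasome (0.0354; 0.898).

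Fed lungs of 2, 4 and 12 h differed from those of 0 h. The hour cannot be separated here from other differences of the fed 0 h arrays, such as their Gapdh ratio. Clock genes differed in fed mice between 0 and 12 h: Per2, at the floor on 2 of 4 fed 0 h arrays, rose at least 4.84-fold (adjusted p = 0.00347), Per1 2.82-fold (0.00843), Nr1d2, which encodes the repressor Rev-erb beta, 2.69-fold (0.00513), Tef 2.12-fold (0.0459) and Cry1 2.0-fold (0.0111), and Arntl, the activator BMAL1, fell 2.0-fold (0.019). At 4 h Dbp, a clock output factor, rose 5.69-fold over 0 h (3.52 to 9.21; 0.00163), from 164 ± 39 to 912 ± 96, with a rise of Nr1d2 (2.69-fold, 0.0104) and Bhlhe40 and a fall of Arntl. CR lungs of the same hours had like levels, 1010 ± 8 for Dbp at 4 h and 444 ± 66 for Per2 at 12 h against 486 ± 15 in fed mice, but whether they were equal was not tested. The log2 differences of CR from fed were 0.15 ± 0.38 for Dbp at 4 h and -0.14 ± 0.42 for Per2 at 12 h (± SE). Of the 18 clock genes 5 rose and 1 fell at 12 h, 8 and 1 adjusted over the list alone (0.000168; 0.292 with an estimated correlation; 0.0956 against number 2).

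In late CR, at the clock time of fed 0 h, Dbp was at the floor on 7 of 8 arrays, at least 1.98-fold lower (adjusted p = 0.00878). Arntl was 1.51-fold higher (0.0114), Cry1 1.64-fold (0.00162), Per2 at least 1.93-fold (0.018) and Per1 4.08-fold (1.08e-06). Against fed 0 h number 2 Arntl (0.136) and Per2 (0.27) did not pass, and the clock list had an adjusted p of 0.826. Clock genes also differed between the fed 0 h numbers, 7 of 18 being lower in number 1 (0.0473). Cirbp, a cold-inducible RNA-binding protein, fell 2.07-fold in fed 12 h (0.0019), from 2236 ± 260 to 1074 ± 17, and rose 1.42-fold in late CR (0.00445), to 3236 ± 753. It was the only measured gene of the cold-inducible list, which was not tested as a list.

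**Figure D3:**
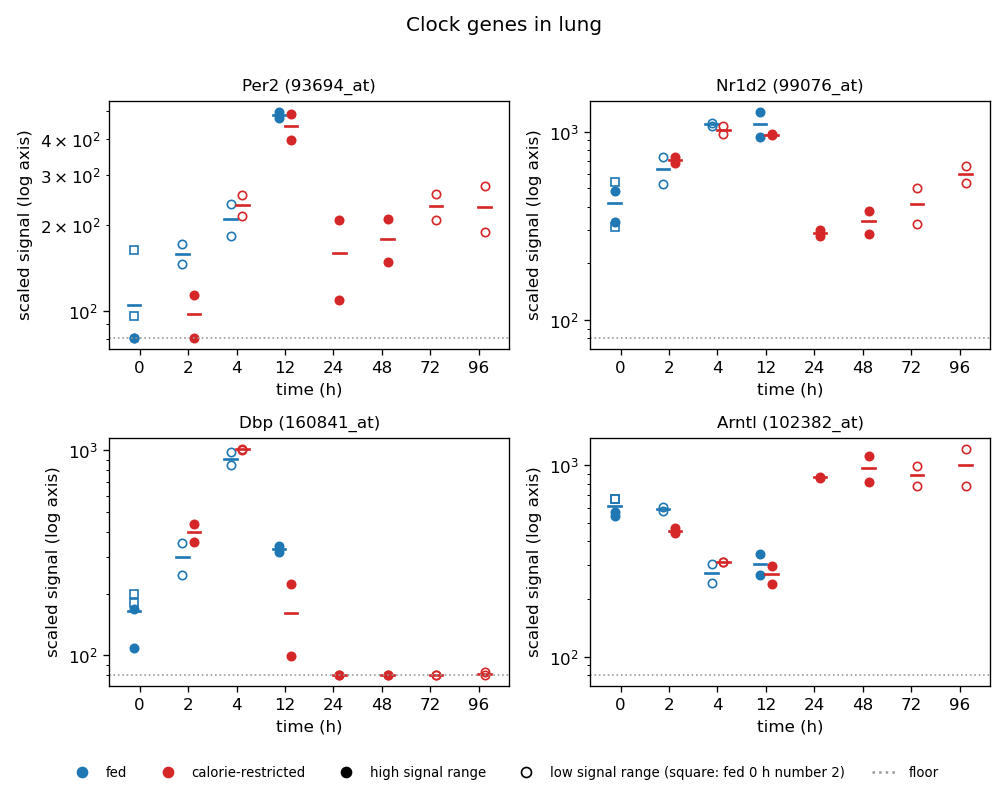
Scaled signal per array (log axis) of the clock genes Per2, Nr1d2, Dbp and Arntl against hours, with fed arrays in blue, CR arrays in red, filled points for the high and open points for the low signal range, squares for fed 0 h number 2, short bars for group means and a dotted line for the floor. Dbp averaged 164 in fed 0 h, 912 in fed 4 h and 1010 in CR 4 h and lay at the floor of 80.37 in CR 24, 48 and 72 h.

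Between fed 12 h and fed 0 h 143 probes changed, 76 up and 67 down. Map3k6 (5.35-fold, adjusted p = 0.0019), Fkbp5 (4.75-fold, 5.12e-05) and Zbtb16 (3.9-fold, 0.0303), which were also among the late CR rises, were higher in fed 12 h, as were the inducible heat shock genes Hspa1b (4.74-fold, 0.00379) and Hspa1a (3.47-fold, 0.022). Rangap1 rose at least 4.65-fold (0.0265) from the floor on all 4 fed 0 h arrays, while its other probe did not pass (log2 0.38, 0.37). Cyth3, at the floor on 3 of 4 fed 0 h arrays, rose at least 4.61-fold (0.0111), Tgfb1, a growth factor of matrix production, 4.29-fold (0.0425) and Clca1 3.04-fold (0.0413). Kdm1a (at least 5.23-fold) and Gmppb (at least 4.12-fold) fell to the floor, and Cars fell at least 4.44-fold, Nsmf 4.32-fold, Akr1c13 4.06-fold and Coq4 at least 3.32-fold. Hdc, the enzyme that makes histamine, fell 2.7-fold (5.12e-05), from 2938 ± 205 to 1098 ± 207. Krt32, Atp5md and Ccdc90b fell 2.58-, 2.57- and 2.53-fold. Against number 2 Tgfb1 (log2 1.52, 0.0752) and Clca1 (1.23, 0.0718) did not pass.

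Of 37 heat shock and chaperone genes 6 rose and none fell in fed 12 h, 7 adjusted over the list alone (adjusted p = 0.000468; 0.211 with an estimated correlation), against number 1 with 0.0575. Of 27 endothelial genes Ace, Lyve1 and Thbd rose, 11 rose and 2 fell adjusted over the list alone (1.01e-05; 0.292 with an estimated correlation). Of the glucocorticoid list Fkbp5, Zbtb16 and Per1 rose, 6 rose and 1 fell adjusted over the list alone (0.0074; 0.211 with an estimated correlation), and against number 1 the adjusted p was 0.0823. Oxidative phosphorylation (2 of 64 fell, 3 adjusted over the list alone; 7.15e-08; 0.806 with an estimated correlation), proteasome (1 and 2 fell; 0.0074; 0.806) and ribosomal protein genes (none; 0.0431; 0.806) were lower, with 0.954, 0.638 and 0.0567 against number 2, where the last 2 lists pointed up.

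The balance of rises and falls in fed 12 h depended on the scaling. Rises made up 53.1% with median scaling, 66.7% (126 up, 63 down) with quantile normalization and 71.1% (140 up, 57 down) with the values as deposited. Against number 1, which shares the signal range of fed 12 h, 2304 probes changed, and against number 2 649. Leaving out 1 array moved the count of 143 to between 18 (without fed 12 h 1a) and 337 (without fed 0 h 2b), with 318 without fed 0 h 2a. At 2 h 6 probes differed from fed 0 h: Fkbp5 (3.03-fold, adjusted p = 0.00723) and Apbb1ip (2.01-fold, 0.0156) rose and Cars (at least 3.62-fold, 0.038), Calml4 (2.7-fold, 0.00723), Myl4 (1.96-fold, 0.0342) and Tnni3 (log2 -0.78, 0.0342) fell. At 4 h 15 probes rose and 8 fell. Besides Dbp and Nr1d2 the largest rise was that of Trav9d-3 (at least 4.75-fold, 0.0134), and the largest falls were those of Ddx6, an RNA helicase (3.37-fold, 0.00237), Nfatc3 (2.93-fold, 0.0104) and Ica1 (2.77-fold, 0.049). The other probes of Myl4 (log2 -0.14), Trav9d-3 (0.57) and Ica1 (0.22) did not pass, nor did 1 of 3 probes of Ddx6.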

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

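Of the tests weighed here, those on the 3'/5' ratio, on the signal range and the daily rhythm of the glucocorticoid list, on the muscle genes, and the splits that keep a and b together were chosen after the result was seen.

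Of 60 probes named in the text and tested over the 4 fed 0 h arrays, 6 had 1 array far from the other 3, and chance flags about 1 in 20 groups of independent values. That rate is only a guide here, as the 4 arrays form 2 pairs that differ at many probes. Grik5 was at 418.9 on array 1b and at 842 to 904 on the others, and Sorbs3 at 538.3 on 2b and at 80.37 to 139.1 on the others. Cyth3 was at 124.1 on 1b and Trav9d-3 at 113.7 on 2b, with the other 3 arrays at the floor of 80.37, where any value above the floor stands out. Clca1 was at 581.7 on 2b against 241.1 to 293.7, and Apbb1ip at 714.6 on 2a against 992.5 to 1032. Between CR 24, 48, 72 and 96 h the level differed (moderated F test, limma) for Cyp1a1 (adjusted p = 8.94e-05), which was 4774 ± 1831 at 72 h and 317 to 626 at the other times. Pheta1 (0.000496) was at 106.3 ± 3.6 at 48 h and at 409 to 589 otherwise, and Igha (0.00171) at 645 ± 96 at 48 h and at 1393 to 1981 otherwise. The CR 48 h arrays also had high 3'/5' ratios (actin 3.81 and 2.69, Gapdh 1.95 and 2.15). Apbb1ip, Mrc1 and Ddit4 differed too (0.00395 each). Apbb1ip and Mrc1 were highest at 72 and 96 h, whose arrays have the low signal range. Ddit4 rose from 24 h, of the high range, to 96 h, of the low one.

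The fed 0 h arrays numbered 1 and 2 differed at 2969 probes, by a median of 0.935 log2. The signal range of the arrays is argued against, because over these probes the other groups of high and low range differed by a median equal to 1.52% of that difference, and by -5.87% to 6.13% with 1 group left out. The shape of the signal distribution is argued against as well, since after quantile normalization the number of differing probes was 100% of the number before. RNA degradation read as a 3' bias is argued against by a 3'/5' difference of 0.108 log2, below the median a to b difference of 0.195. No biological explanation was tested, and different animals, days of dissection or RNA preparations may account for it.

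The glucocorticoid response list was higher in late CR. The values argue against the signal range (larger adjusted p within the ranges, 5.42e-06). They also argue against a low level in the fed 0 h arrays alone (3.38e-20 against fed 2, 4 and 12 h). Both tests used the preset correlation only. A shifted daily rhythm stays open: of the 19 genes that rose, 18 (94.7%) exceeded every fed group mean, but the fed times span only 0 to 12 h. Circulating hormone was not measured in the data used here, so a rise of corticosterone under food restriction is a hypothesis without a test.

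Of the muscle genes, the 7 that fell in late CR (median log2 -0.83) were also lower in fed 2, 4 and 12 h, by 74.7% of the late fall (66.9 to 74.1% with 1 gene left out), and in CR 2, 4 and 12 h (median log2 -0.64). The genes were picked for a fall from the same fed 0 h arrays, which alone lowers the other groups: for 482 other genes that fell in late CR the value was 53.1%, and 74 of 1000 draws of 7 such genes reached that of the muscle genes. More heart muscle in the fed 0 h samples than in every other group, as heart or the muscle sleeve of pulmonary veins may come with a lung, therefore stays open. Over the whole list, late CR lay at a median log2 of -0.08 from fed 2, 4 and 12 h (camera, 3 rose, 1 fell, adjusted p = 0.726). Myl7 was at 9524 ± 1512 in fed 0 h, 5474 ± 871 in fed 2 to 12 h and 4142 ± 1307 in late CR, and none of the 7 genes is in another list. The heart myosin gene Myh6, 1 member of the list, was at 537 ± 75 in fed 0 h number 1, 2370 ± 658 in number 2 and 2086 ± 518 in late CR. It lay below late CR in number 1 only, so this gene does not decide the question. Within the low signal range the list fell (median log2 -0.46, 8 fell, 0 rose, adjusted p = 8.2e-06). This argues against the signal range as the cause at CR 72 and 96 h. Within the high range the median log2 was -0.30 (6 fell, 3 rose, 0.662), so for CR 24 and 48 h the signal range stays open.

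Other splits of the same arrays into groups of the same sizes were tried, 100 drawn of 495 for the late and of 108 for the early comparison. In the late mean the real split gave 1346 probes (highest other 1794; 3 of 100 splits gave as many, the real one included) and 15 lists (highest other 14; 1 of 100). In the early mean it gave 2 probes (highest other 1; 1 of 100). These splits exchange single arrays, which counts a and b as separate samples, and they may be repeat arrays of 1 RNA. With a and b kept together there are 15 late and 4 early splits, too few for a share under 0.05. There the late real split gave 1346 probes (highest other 1488) and 15 lists (highest other 17), and the early one 2 probes (highest other 0). The split with 1488 probes put CR 72 and 96 h, which have the low signal range, in the place of the controls, and within that range 793 probes changed against number 2. Both larger splits of single arrays, with 1532 and 1794 probes, put fed 0 h 1a and 1b with 2 CR arrays, but other splits of that make-up gave as few as 0, and the cause was not tested. Against number 1 alone 3679 probes changed and against number 2 577. For the early lists chance was not excluded (3 lists, highest other 9; 43 of 100).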

How the results depend on the processing

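The alternatives with separate or single fed 0 h numbers, with controls of the same signal range, with that range as a block, and with 4 and 12 h only were chosen after seeing the data. Of 1626 values of 72 named gene and comparison pairs, 1369 kept direction and side of the threshold, 254 kept only the direction and 3 reversed. With fed 0 h in place of fed 12 h as control, the values reversed were Cars, CR 12 h against fed 12 h (-0.03617 log2), Kdm1a, CR 12 h against fed 12 h (-0.2866) and Nsmf, CR 12 h against fed 12 h (-0.2711), where the other control shows the cause. For the other changes the cause was not tested, except that fewer arrays or groups leave fewer degrees of freedom. The floor limits what dim probes can show, and a group left with 1 array is assumed to vary like the others.

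Probe counts moved by over 1.5 times as follows. With quantile normalization, 2 probes differed between early times. With the floor at the 40th percentile CR 12 h gave 6. With no filter on dim probes CR 2 h gave 2, CR 12 h 36, the early mean 10, the early F test 19 and the late F test 88. For eBayes without a trend CR 12 h gave 6 and the early mean 0. With array weights CR 2 h gave 5, CR 4 h 4, CR 24 h 83, CR 48 h 154, CR 96 h 239, the late mean 288, fed 12 h 28, the early F test 32 and the late F test 238. With only the groups compared in the fit CR 12 h gave 0, CR 24 h 1, CR 48 h 0, CR 72 h 12, CR 96 h 20, the early mean 1, the late mean 347, fed 12 h 0, the early F test 29 and the late F test 65.

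With the letter as a replicate block CR 12 h gave 7 and the early mean 1, and no other count moved; a minus b differences of 2 groups correlated across probes at -0.19 to 0.123 (66 pairs), so the letters did not pair the arrays. With a and b averaged to 1 sample the late mean gave 27 (1095 at an unadjusted p under 0.05, smallest adjusted p 0.00113) and the early mean 0 (211, 0.162). In these fits the late times formed 1 group, and the early fit took the hour as a block. The lower counts are thus not the effect of averaging alone.

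Late single times stand for probes changed, CR 24 h against fed 0 h, probes changed, CR 48 h against fed 0 h, probes changed, CR 72 h against fed 0 h, and probes changed, CR 96 h against fed 0 h. With the mean of the 4 fed groups as control CR 24 h gave 101, CR 72 h 139, CR 96 h 290 and the late mean 797. With fed 0 h as control CR 2 h gave 21, CR 4 h 67, CR 12 h 698 and the early mean 359. With fed 0 h number 1 as control CR 24 h gave 2895, CR 48 h 3142, CR 72 h 3049, CR 96 h 2896, the late mean 3679 and fed 12 h 2304. With number 2 CR 48 h gave 260, the late mean 577 and fed 12 h 649. With the numbers as separate groups CR 24 h gave 1340, CR 48 h 1671, CR 72 h 1660, CR 96 h 1605, the late mean 2543 and fed 12 h 864. With a control of the same signal range CR 24 h gave 2895, CR 48 h 3142 and fed 12 h 2304. With the signal range as a batch block, which rests on the fed 0 h numbers alone, CR 2 h gave 800, CR 12 h 36, CR 24 h 2895, CR 48 h 3142, the early mean 452, the late mean 2543, fed 12 h 2304, the early F test 136 and the late F test 1785. In CR 2 h, the early mean and the F tests, this block subtracts the difference of those numbers. The other groups of high and low range did not show that difference as a whole. With 4 and 12 h only the early mean gave 1.

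Lists shifted with an estimated correlation were 1 (early), 3 (late) and 0 (fed 12 h), against 3, 15 and 7. With fry they were 1 (early) and 4 (fed 12 h). With 4 and 12 h only the early number was 9, with the signal block 11, and with number 2 as control the late number was 9.

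Late single times again stand for probes changed, CR 24 h against fed 0 h, and so on to probes changed, CR 96 h against fed 0 h. Leaving out 1 array gave 0 to 1 probes at CR 2 h and at CR 4 h, 1 to 12 at CR 12 h, 37 to 744 at CR 24 h, 93 to 1239 at CR 48 h, 61 to 1088 at CR 72 h and 83 to 1017 at CR 96 h. It gave 0 to 3 in the early mean, 542 to 2248 in the late mean, 18 to 337 for fed 12 h, 0 to 0 in the early F test and 12 to 50 in the late one. Lists were 1 to 4 (early), 12 to 16 (late) and 5 to 9 (fed 12 h).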

Other observations

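The test of B-cell genes was chosen after the result was seen, and that of the 12 h effect before.

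Several other lists did not shift as a whole in late CR against fed 0 h. Of 22 macrophage and monocyte genes (list adjusted p = 0.092) Ccr2, the monocyte chemokine receptor, was 2.19-fold lower (0.000154) and the class II antigen genes H2-Aa, H2-Ab1 and H2-Eb1 were 1.71-, 1.83- and 1.77-fold lower. The list was lower within the high signal range (18 of 22 fell, 5.35e-06) and higher within the low one (10 rose and 3 fell, 0.00192). None of 10 T-cell genes (0.891) or 11 erythroid genes (0.274) passed. Of 14 adipose genes Lpl, the lipases Lipe (2.19-fold) and Pnpla2 (2.14-fold) and Cyp2e1 rose, and Car3 (2.36-fold), Adipoq, the adipocyte hormone adiponectin (1.88-fold), and Scd1 fell (list 0.792). Of 26 matrix protease and inhibitor genes 6 rose, among them Adam19 (2.07-fold, 0.00785) and Timp3 (1.65-fold, 0.00118), and Mmp12, the macrophage elastase, fell 1.77-fold (0.014; list 0.274). Of 41 antioxidant and xenobiotic genes 7 rose and 5 fell (0.891).

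The further array of another platform, whose title gives 3 h of CR and whose description speaks of refeeding after 14 days of CR, held 45101 probe sets with a median signal of 96.1 and a highest signal of 19260. Its Sftpc probes were at 14880 and 1096. Fkbp5 read 196, 230 and 9.89 on its 3 probes, Pdk4 57.9 and Klf9 up to 1184. No control array of this platform was in any group, so nothing was compared.

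A hypothesis was that the lung had fewer B cells from 12 h of CR on. The list of B-cell genes was lower at 12 h and within both signal ranges at 24 to 96 h, with a largest adjusted p of 0.0152. This repeats the observation that prompted the hypothesis and does not test the number of cells, so the hypothesis stays open. At 24 h alone the list did not pass (0.0572, 0 of 15 genes fell; 0.713 against fed 0 h number 2), nor at 96 h against number 2 (0.0516). With an estimated correlation it did not pass either, at 0.102 for 12 h and 0.129 for the late mean. Cd79b was at 534 ± 83 in CR 12 h against 1116 ± 13 in fed 12 h, and Ms4a1 at 729 ± 42 against 1551 ± 419. Within the high range 9 of the 15 genes fell and within the low range 3, and 0 rose in either. Pax5, which fell at 12 h, had late log2 changes of -0.10 against number 1 (limma, adjusted p = 0.723) and -0.69 against number 2 (0.0471). Igha, an immunoglobulin gene outside the list, was higher in late CR against number 1 (1.04, 1.48e-05) and number 2 (1.06, 0.000133). Lower expression per cell and blood left in the vessels of the sampled lung remain open too, and no cell count was used here.

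A further hypothesis was that the late response was already present at 12 h. Across 5706 genes, which are not independent replicates, the 12 h effect correlated with the late effect at Pearson r = 0.25 (Spearman rho 0.248). The 4 h effect gave 0.259 and the 2 h effect -0.246, so the value does not set 12 h apart and the question stays open.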
